A study of Arabidopsis thaliana with 23 samples.

How the data were processed

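The data were RNA-seq gene counts from Arabidopsis thaliana of the Col-0 background. Of the 23 samples in the series, 15 were RNA-seq libraries and 8 were CUT&Tag samples for H3K27me3 or IgG, which were not analysed here. The 6 seedling libraries formed 2 groups, DMSO and rac-GR24, and the 9 libraries of axillary tissue formed 3 groups, intact wild type (WT), intact brc1-2 and decapitated WT, with 3 libraries in each group. Groups were taken from the sample labels. In the axillary table, 2 columns carried the same replicate number for brc1-2, so they were used as brc1-2 libraries with no number of their own and are called 2a and 2b. The labels do not say whether the libraries of a group came from separate plants or cultures, so p-values measure the spread between these samples, which may be technical.

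The authors deposited whole-number counts per gene in 2 tables, with exon coordinates and lengths laid out as featureCounts writes them, per the file headers. The submitters' processing notes name TAIR10, cutadapt 3.5, HISAT2 2.0.5, SAMtools 1.13, featureCounts 2.0.1, DESeq2 1.32.0 and fastp 0.23.1, without their order or settings. Whether the counting used strand is not given in the sources used here, so a gene and an antisense partner cannot be told apart. The axillary table held 32833 genes. The seedling table held 32224 complete genes and ended in 1 incomplete line, and 609 genes of the axillary table were not in it, of which 324 lay on chromosome 4, 152 on the mitochondrial and 133 on the plastid chromosome. Seedling values therefore cover those 32224 genes. Of all identifiers, 32548 matched the reference gene table and 10804 had a symbol there; other genes are named by identifier.

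Between 60.8% and 71.8% of counts from 1 to 20 were even in each library, as when each mate of a read pair is counted. A count is then not an independent fragment, and intervals and floors, which cover counting error only, are too narrow. The test takes its spread from the libraries. Halving the counts was run as an added alternative, which scales all libraries alike.

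Total counts ran from 31209344 to 44442493 per seedling library and from 47462342 to 61228766 per axillary library. No pair of libraries in a group matched within sampling noise, with chi-square per degree of freedom from 3.05 to 19.03 over genes with at least 100 counts in the pair.

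Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 9 axillary libraries shared one fit and the 6 seedling libraries another. This left 21063 genes in seedlings and 21539 in axillary tissue, with a common biological coefficient of variation of 8.92% and 5.11%. The 2 tables were tested separately. A rise or fall named below passed this test. Where a group had no counts for a gene, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 the ratio is given with its 95% counting interval.

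Before the data were examined, 24 gene lists with 479 entries were written from general knowledge, together with the choice of tests and of named genes. They cover the strigolactone and karrikin pathway, the BRC1 and HD-ZIP module, the responses to abscisic acid, cytokinin, auxin, gibberellin, jasmonate and salicylic acid, bud dormancy, the cell cycle, ribosomal proteins, Polycomb complexes with H3K27 demethylases, classical Polycomb targets, NF-Y subunits, flowering, the shoot meristem, flavonoids, heat shock and the clock, and markers of leaf photosynthesis, root, secondary wall, tapetum with pollen, and seed storage. Of these, 2 entries were dropped because the reference gave the identifier another symbol, and 477 were used. Lists were tested against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The entry written as HB21 is AT2G02540, which shares that symbol with the HD-ZIP gene AT2G18550; the list was kept as written, and AT2G18550 was looked up after its values were seen. Named genes were the 6 largest rises and 6 largest falls per comparison (4 for decapitated WT against brc1-2) among genes past the threshold with a mean of at least 1 CPM and libraries that did not overlap, the BRC1 list with DLK2, KUF1, BBX20 and 4 SMXL genes whatever their p, and the 2 to 4 members with the smallest p in each list described. Floral organ genes, MYC2, COL1 and library counts of seed genes given outside this rule were chosen after their values were seen.

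Alternatives were DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom, 2 other filters, 2 other thresholds, a fit of only the groups compared, a replicate block and leaving out each library. On simulated counts for rac-GR24 against DMSO, over 20886 genes, the test recovered 74.6% of genes changed 1.5-fold and 97% of those changed 4-fold, with 25 false calls. For brc1-2 it recovered 70.1% and 95.5% over 21332 genes, with 14 false calls, and for decapitation 67.2% and 93.9% over 21330 genes, with 11. Each simulation changed only 67 genes 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. In each, false calls made up a larger share of all calls than the threshold of 0.05, most so for rac-GR24. The test was therefore less strict on simulated counts than its threshold states. The share of genes changed in the simulations was far below the share called in the data. The false share among the calls in the data was not measured and may also exceed 0.05.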

Results

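Gene expression was measured by RNA-seq in Arabidopsis. Whole seedlings were grown for 7 days on rac-GR24, a synthetic strigolactone analogue, at 2.5 µM, or on its solvent DMSO. Axillary tissue, meaning buds with the leaf axil below them, came from intact WT plants, intact brc1-2 mutants and WT plants whose main shoot had been removed. Each group had 3 libraries. Total counts per library ran from 31209344 to 44442493 in seedlings and from 47462342 to 61228766 in axillary tissue. The seedling and axillary samples carry different batch labels and were tested separately. Values in parentheses after a gene name are log2 changes, with SE where given, at n = 3 per group. SE was calculated back from the test, as the size of the log2 change over the square root of its F statistic. It is not a direct standard error of the estimate and may be too narrow where a group held few counts.

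BRC1 (AT3G18550; TAIR10 chromosome 3, 6383289 to 6385815), a TCP transcription factor that represses bud outgrowth, is the gene disrupted in brc1-2 and was read first. Intact WT libraries held 392, 373 and 423 counts and brc1-2 libraries 2, 4 and 2 (-7.20 ± 0.26; edgeR quasi-likelihood adjusted p = 1.9e-19). After decapitation the counts were 95, 99 and 77 (-2.12 ± 0.15; edgeR adjusted p = 5.7e-13). DMSO seedlings held 0, 0 and 2 counts and rac-GR24 seedlings 279, 140 and 94, a ratio of 249 with a 95% counting interval of 68.7 to 2060 (edgeR adjusted p = 6.1e-07). Without DMSO replicate 3, which held the only counts of its group, the fitted log2 change went from 7.67 to 10.29, a value that then depends on the prior count.

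**Figure D1:**
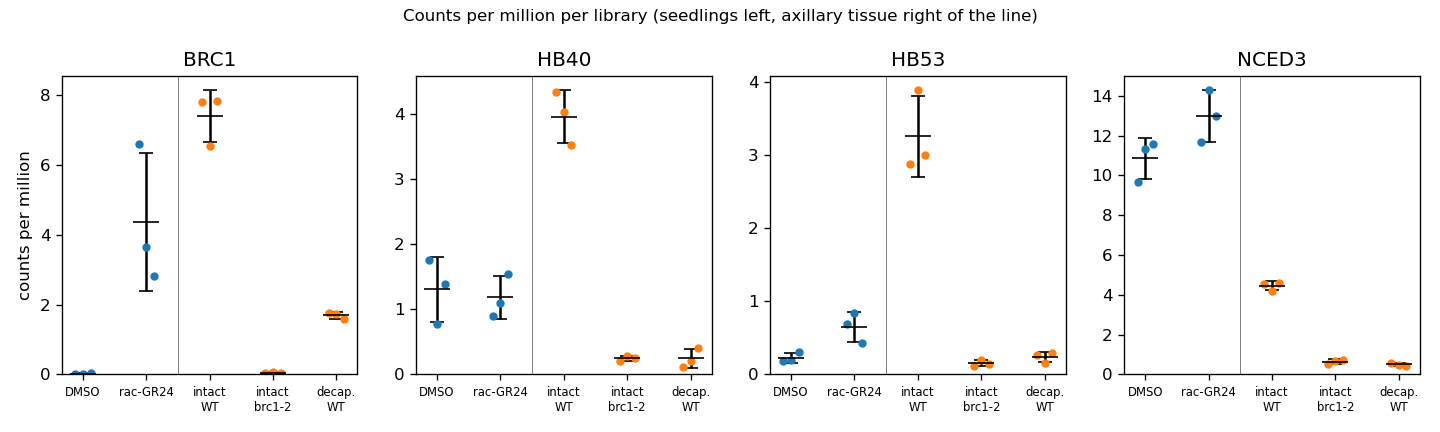
CPM of BRC1, HB40, HB53 and NCED3 in each library (points), with the mean (long line) and SD (whiskers) of 3 libraries per group; each panel has its own linear axis from 0, with seedlings left and axillary tissue right of the line. BRC1 had a mean of 7.40 CPM in intact WT, 0.0481 in brc1-2 and 1.69 after decapitation.

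The first comparison asks which transcripts respond to rac-GR24 in seedlings. Genes of strigolactone and karrikin signalling rose, among them DLK2 (3.99 ± 0.13), a paralog of the strigolactone receptor, which went from 2.80 to 43.8 CPM. BBX20 (2.48 ± 0.15), KUF1 (1.33 ± 0.11) and the genes of the repressors SMXL2 (1.25), SMXL6 (1.36), SMXL7 (1.03) and SMXL8 (1.52) also rose. Of 18 members of this list 9 rose, 3 fell and 6 did not pass (camera adjusted p = 2.8e-17; adjusted p = 0.008 with an estimated correlation). Flavonoid and anthocyanin genes rose in 14 of 19 cases with 0 lower, including the pigment pathway genes DFR (2.27 ± 0.07), TT7 (2.19), GSTF12 (2.21) and LDOX (2.37). Their list was called by both tests (camera adjusted p = 1.4e-44; adjusted p = 0.0032 with an estimated correlation). Auxin response and transport genes fell in 20 of 29 cases and rose in 2, with IAA19 (-2.09 ± 0.16), IAA1 (-1.15) and the auxin carrier gene PIN7 (-0.89) lower (camera adjusted p = 1.5e-14; adjusted p = 0.039 with an estimated correlation).

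Other lists were called for rac-GR24 with the preset correlation alone. Abscisic acid response genes rose in 14 of 22 cases with 0 lower, including RD26 (1.80) and RD20 (1.55) (camera adjusted p = 3.8e-12; adjusted p = 0.086 with an estimated correlation). Cell cycle and DNA replication genes fell in 26 of 38 cases with 0 higher, including CYCD1;1 (-0.72) and MCM7 (-0.48) (camera adjusted p = 1.1e-10; adjusted p = 0.29 with an estimated correlation). Bud dormancy and sugar starvation genes rose in 8 of 17 cases, including PRODH1 (1.52), while SEN1 (-0.96) fell (camera adjusted p = 5e-04; adjusted p = 0.42 with an estimated correlation). Leaf photosynthesis genes fell in 14 of 25 cases, including RBCS3B (-0.46), which has near-identical copies (camera adjusted p = 0.00062; adjusted p = 0.61 with an estimated correlation). Root markers rose in 5 of 11 cases, including PYK10 (0.78) (camera adjusted p = 0.00043; adjusted p = 0.086 with an estimated correlation).

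Seed storage markers rose in 6 of 9 cases (camera adjusted p = 0.0049; adjusted p = 0.42 with an estimated correlation), with uneven libraries. CRA1, a cruciferin gene, had 64, 20 and 42 counts on DMSO and 332, 96 and 854 on rac-GR24, and its log2 change of 3.36 became 2.17 without rac-GR24 replicate 3. Circadian clock genes rose in 5 of 16 cases, including RVE1 (0.78) (camera adjusted p = 0.03; adjusted p = 0.34 with an estimated correlation). Secondary wall markers of stem fell in 5 of 16 cases, including VND6 (-1.48) (camera adjusted p = 0.021; adjusted p = 0.42 with an estimated correlation). Without DMSO replicate 3 the camera calls of both the clock and the secondary wall list ended (adjusted p = 0.084 for each), and the clock call also ended without rac-GR24 replicate 3 (adjusted p = 0.05). Adjusted over the list alone, 3 auxin genes rose, 20 photosynthesis genes fell, 8 clock genes rose, 16 flavonoid genes rose and 2 fell, and 10 strigolactone genes rose and 4 fell, and the counts of the other lists above were the same.

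AT1G30250 was at least 93.3-fold higher on rac-GR24, the cell wall invertase gene CWINV5 (6.74 ± 0.21) rose and PEPC1 (-3.46 ± 0.29) fell. In the BRC1 list, HB53 rose (1.47 ± 0.47; edgeR adjusted p = 0.035), a call that ended without DMSO replicate 1 (0.11), DMSO replicate 2 (0.11), rac-GR24 replicate 1 (0.1) or rac-GR24 replicate 2 (0.14), and with DESeq2 (0.062). HB40 (-0.17), BRC2 (-0.27) and NCED3 (0.25) did not pass, and the BRC1 list was not called for rac-GR24 (camera adjusted p = 0.12; adjusted p = 0.47 with an estimated correlation). The HD-ZIP gene HB21 (AT2G18550), looked up afterwards, rose (2.26 ± 0.40). Of 21063 genes tested 2604 rose and 2456 fell at an edgeR adjusted p under 0.05, and 429 and 339 of these changed at least 2-fold.

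The second comparison asks what differs in axillary tissue when BRC1 is lost. HB40 (-4.00 ± 0.28), HB53 (-4.37 ± 0.30) and NCED3 (-2.80 ± 0.20), the gene of a rate-limiting enzyme of abscisic acid synthesis, fell from 3.96, 3.26 and 4.45 CPM in intact WT. In the BRC1 list 4 of 6 members fell, BRC1 included, and 2 rose (camera adjusted p = 0.00074; adjusted p = 0.04 with an estimated correlation). The fall of BRC1 itself is set by the genotype. Without BRC1, a test chosen after the data were seen, the list was called with the preset correlation alone (camera adjusted p = 0.042; adjusted p = 0.17 with an estimated correlation). The 2 that rose were BRC2 (0.44), whose call ended with a trend on gene length removed (0.13), and AT2G02540, written as HB21 (0.35), whose call ended without intact WT replicate 3 (0.22). The HD-ZIP gene HB21 (AT2G18550) fell (-3.69 ± 0.24). Abscisic acid response genes fell in 20 of 21 cases, including HAI1 (-1.78), COR15A (-1.22) and RD20 (-1.21) (camera adjusted p = 5.3e-12; adjusted p = 0.0025 with an estimated correlation). Jasmonate and wounding genes fell in 18 of 25 cases and rose in 2, with the defensin gene PDF1.2A (-5.14 ± 0.06), JAZ9 (-1.26) and AOS (-1.23) lower (camera adjusted p = 4.8e-18; adjusted p = 0.0013 with an estimated correlation). PDF1.2A and PDF1.2c (-6.30) are similar copies whose reads are uncertain.

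Cell cycle and DNA replication genes rose in 31 of 38 cases and fell in 2, with HINKEL (1.21), CDC20.1 (0.90) and MCM2 (0.86) higher (camera adjusted p = 1.5e-08; adjusted p = 0.019 with an estimated correlation). Tapetum and pollen markers, written as markers of anthers, rose in 9 of 9 cases tested, of 13 written (camera adjusted p = 5.8e-08; adjusted p = 0.0094 with an estimated correlation). ATA7, VGD1 and VGDH1 held 0 counts in every axillary library and GRP17 at most 8, so these were not tested. MS1 and CYP703A2 held 0 counts in both WT groups and passed the filter through brc1-2 alone. A9 and CYP704B1 also passed through the brc1-2 libraries. After decapitation A9 held 7, 7 and 14 counts and CYP704B1 11, 6 and 2, with at most 3 in intact WT. The rise of MS1, CYP703A2, A9 and CYP704B1 is therefore no independent support. Among the members that rose, A9 (7.06 ± 0.42) reached 3.61 CPM and LAP5 (4.44 ± 0.29) 4.08 CPM. Some members were not particular to axillary tissue: LAP6 held 58 to 116 and AMS 16 to 41 counts in every seedling library. AT5G52160 and MEE48 were at least 975-fold and at least 427-fold higher than in intact WT. Flavonoid and anthocyanin genes fell in 10 of 22 cases and rose in 4, with PAP1 (-1.87), a MYB activator of the pathway, and DFR (-1.12) lower (camera adjusted p = 0.0037; adjusted p = 0.048 with an estimated correlation, and 0.057 with BRC1 also left out of the BRC1 list).

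Leaf photosynthesis genes rose in 23 of 25 cases in brc1-2, including LHCB1.1 (0.67), which has near-identical copies (camera adjusted p = 6.1e-06; adjusted p = 0.28 with an estimated correlation). Cytosolic ribosomal protein genes rose in 15 of 17 cases, including RPS6A (0.40) (camera adjusted p = 0.0037; adjusted p = 0.49 with an estimated correlation). Genes of Polycomb complexes and H3K27 demethylases rose in 10 of 17 cases and fell in 1, with the methyltransferase gene CLF (0.50) and the demethylase gene ELF6 (0.57) higher (camera adjusted p = 0.025). That call was lost at adjusted p = 0.1 with an estimated correlation and at adjusted p = 0.21 with the length trend removed. NF-Y subunit genes fell in 14 of 22 cases and rose in 2, with NF-YA3 (-0.61) lower, and the list was not called (camera adjusted p = 0.15). Of 21539 genes 6546 rose and 6577 fell at an edgeR adjusted p under 0.05, with a median size of 0.39 on the log2 scale among those called, and 589 and 953 changed at least 2-fold. Adjusted over the list alone, the counts of every list named here for brc1-2 were the same.

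The third comparison asks what removal of the main shoot changes in WT axillary tissue. HB40 (-4.03 ± 0.29), HB53 (-3.80 ± 0.29) and NCED3 (-3.14 ± 0.21) fell, as did HB21 (AT2G18550; -3.02 ± 0.23). In the BRC1 list 4 of 6 members fell and 1 rose (camera adjusted p = 0.0036; adjusted p = 0.047 with an estimated correlation). Abscisic acid response genes fell in 21 of 21 cases, including HAI1 (-2.06) and RD20 (-1.87) (camera adjusted p = 1.6e-15; adjusted p = 0.0012 with an estimated correlation). Bud dormancy and sugar starvation genes fell in 14 of 18 cases and rose in 2, with the dormancy markers DRM1 (-2.17) and DRM2 (-3.06) lower (camera adjusted p = 4.7e-07; adjusted p = 0.015 with an estimated correlation). Cell cycle genes rose in 36 of 38 cases, and in 37 adjusted over the list alone, including HINKEL (1.95), CDC20.1 (1.72) and CYCB1;2 (1.43) (camera adjusted p = 7.4e-25; adjusted p = 0.0012 with an estimated correlation). The counts of the other lists named here for decapitation were the same adjusted over the list alone.

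Salicylic acid and defence genes fell in 12 of 16 cases after decapitation and rose in 1, with WRKY70 (-1.46) lower (camera adjusted p = 0.00045; adjusted p = 0.035 with an estimated correlation). Secondary wall markers fell in 16 of 18 cases, including FLA12 (-1.33) and the cellulose synthase gene CESA7 (-0.70) (camera adjusted p = 0.0013; adjusted p = 0.035 with an estimated correlation). Flavonoid genes rose in 16 of 22 cases, including FLS1 (0.61), and fell in 2, including PAP1 (-0.86) (camera adjusted p = 0.0033; adjusted p = 0.046 with an estimated correlation). Jasmonate genes fell in 13 of 25 cases, including PDF1.2A (-2.55), and rose in 5, including VSP1 (1.37) (camera adjusted p = 0.0013; adjusted p = 0.035 with an estimated correlation). Strigolactone pathway genes fell in 11 of 19 cases, including KAI2 (-1.05) and SMXL8 (-0.87), and rose in 3 (camera adjusted p = 0.0038; adjusted p = 0.047 with an estimated correlation). In brc1-2 this list also fell in 11 of 19 cases and rose in 4, without a call (camera adjusted p = 0.13). Nor was it called between decapitated WT and brc1-2 (camera adjusted p = 0.092), so a difference between the 2 effects is not shown. Tapetum and pollen markers rose in 6 of 9 cases with 0 lower, and the list was not called (camera adjusted p = 0.22). Of the 9, MS1 and CYP703A2 held 0 counts in both groups, so they could not move and entered the list test as unchanged. The ERF gene RAP2.6 (7.65 ± 0.24) was among the 6 largest rises.

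Ribosomal protein genes rose in 17 of 17 cases after decapitation, including RPL4D (0.75) (camera adjusted p = 5.2e-15; adjusted p = 0.071 with an estimated correlation). Leaf photosynthesis genes fell in 24 of 25 cases and rose in 1, with LHCB2.1 (-0.75) lower (camera adjusted p = 1.5e-07; adjusted p = 0.18 with an estimated correlation). Polycomb and demethylase genes rose in 13 of 17 cases and fell in 1, with CLF (0.55) and SWN (0.45) higher (camera adjusted p = 0.016). That call was lost at adjusted p = 0.067 with an estimated correlation and at adjusted p = 0.1 with the length trend removed. NF-Y genes fell in 15 of 22 cases and rose in 3, with NF-YB2 (-0.92) lower, a gene that shares 42.8% of its exon bases with another gene (camera adjusted p = 0.043). That call was lost at adjusted p = 0.089 with an estimated correlation, 0.12 with the length trend removed and 0.051 without intact WT replicate 2. Auxin genes fell in 14 of 28 cases, including IAA7 (-0.83), and rose in 8 (camera adjusted p = 0.031; adjusted p = 0.071 with an estimated correlation, and 0.05 without decapitated WT replicate 3). Of 21539 genes 6334 rose and 7222 fell at an edgeR adjusted p under 0.05, and 619 and 1072 changed at least 2-fold. The excess of falls depends on the settings, with 6667 up and 6884 down under DESeq2 size factors, and 6677 up and 6607 down when only the 2 groups were fitted.

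**Figure D2:**
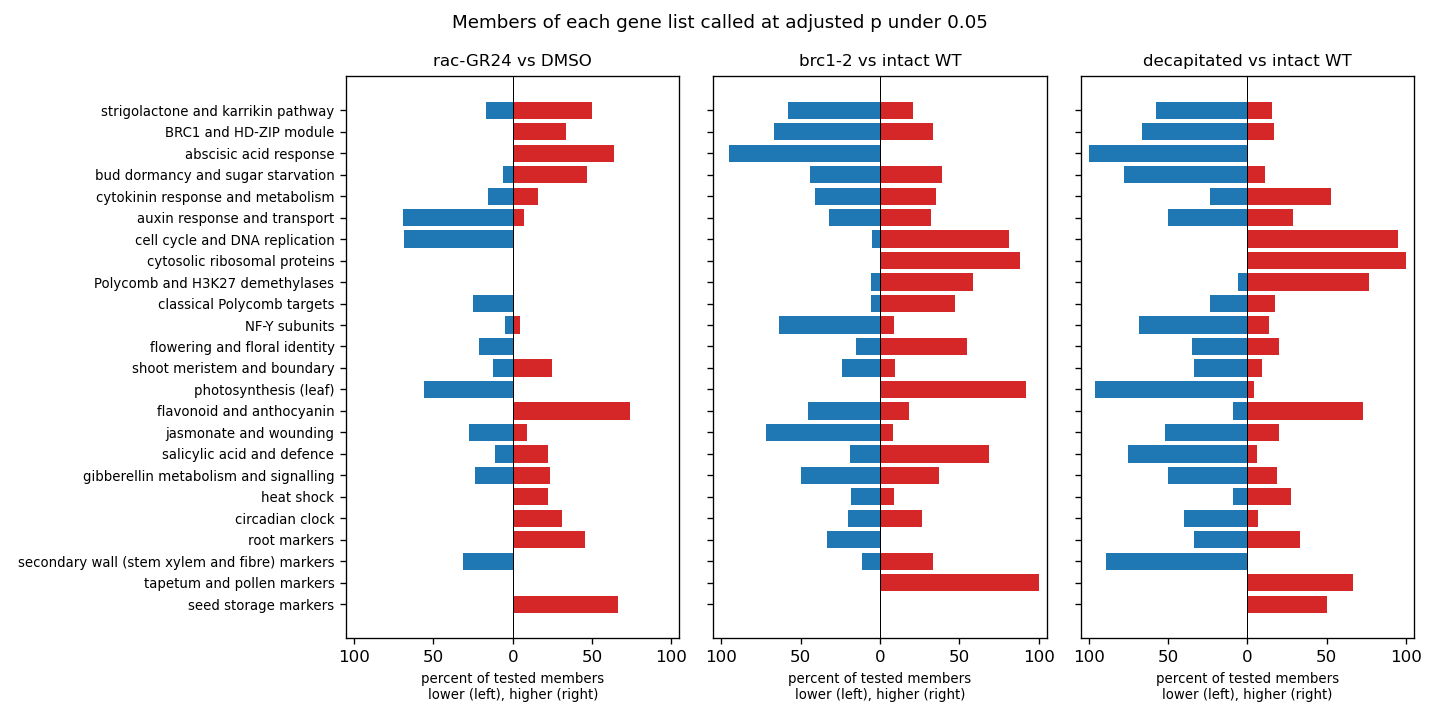
Percent of the tested members of each gene list called higher (red, right) or lower (blue, left) at an edgeR adjusted p under 0.05, for rac-GR24 against DMSO, brc1-2 against intact WT and decapitated against intact WT. Abscisic acid response genes were called higher in 14 of 22 cases in the first panel and lower in 20 of 21 and 21 of 21 in the others.

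Decapitated WT was also compared with brc1-2 directly, which tests the difference between the 2 effects. BRC1 was higher after decapitation (5.08 ± 0.31), while HB40 (-0.03 ± 0.40) and HB53 (0.57 ± 0.42) did not pass. Leaf photosynthesis genes were lower in 25 of 25 cases, including RBCS3B (-0.81), salicylic acid genes in 13 of 16, including WRKY70 (-1.62), and dormancy genes in 15 of 18, including SEN1 (-2.24). Secondary wall markers were lower in 15 of 18 cases, tapetum markers in 8 of 9, including A9 (-4.34), classical Polycomb targets in 12 of 17, including PI (-1.07), and flowering genes in 15 of 20, including SOC1 (-0.46). Of the tapetum markers, MS1, CYP703A2, A9 and CYP704B1 passed the filter through brc1-2, so their lower values here are no independent support. Jasmonate genes were higher in 18 of 25 cases, including VSP2 (1.55), flavonoid genes in 15 of 22, including DFR (1.46), and cell cycle genes in 27 of 38, including CDC20.1 (0.81). These 10 lists were called with both the preset and the estimated correlation, the latter at adjusted p from 0.0015 to 0.044. The Polycomb target and flowering lists are not independent: they share 7 tested genes, AP1 and the 6 floral organ identity genes that were higher in brc1-2 than in intact WT, and all 7 were lower. With the shared genes left out of both, a test chosen after the data were seen, neither list was called (camera adjusted p = 0.13 and 0.14).

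A further 5 lists were called between decapitated WT and brc1-2 with the preset correlation alone. They were ribosomal protein genes (17 of 17 higher; adjusted p = 0.1 with an estimated correlation), cytokinin genes (8 of 17 higher, 1 lower; adjusted p = 0.064) and auxin genes (9 of 28 higher, 13 lower; adjusted p = 0.067). The others were clock genes (1 of 15 higher, 7 lower; adjusted p = 0.1) and root markers (2 of 6 higher, 1 lower; adjusted p = 0.057), whose camera call also ended without decapitated WT replicate 3 (adjusted p = 0.19). Adjusted over the list alone, 19 jasmonate genes were higher and 2 lower, 15 salicylic acid genes, 16 flowering genes and 2 cytokinin genes were lower, and the other counts given for this comparison were the same. Of 21539 genes 5256 were higher and 5192 lower at an edgeR adjusted p under 0.05, and 417 and 797 of these differed at least 2-fold. The balance of directions depends on the settings. With no filter on low counts 6107 were higher and 4685 lower, and with the length trend removed 5647 and 4891.

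Lists not named for a comparison were not called in it, or had too few members there. Gibberellin (4 of 17 higher, 4 lower for rac-GR24; camera adjusted p = 0.74), heat shock (2 of 9 higher; 0.2) and shoot meristem genes (4 of 16 higher, 2 lower; 0.71) were called in none of the 4 comparisons. Adjusted over the list alone, 5 gibberellin genes and 3 shoot meristem genes fell on rac-GR24. For root markers after decapitation the median log2 change (-0.62) and the direction of the uncalled test differed in sign. Tapetum markers in seedlings and seed storage markers in axillary tissue had 2 members tested and no list test. Of these seed markers SESA1 rose after decapitation, with 66, 60 and 37 counts against 0 in each intact WT library, and OLEO4 did not pass.

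Calls were then set against each other. Between brc1-2 and decapitation, 9273 genes moved the same way, 4383 higher and 4890 lower, where independent lists would share 1925 and 2205, and 946 moved in opposite directions. Both comparisons use the same 3 intact WT libraries. In 20 simulations of unchanged groups at most 3 genes were shared, r across genes averaged 0.50 and the covariance 0.0135, against an observed r of 0.586 and covariance of 0.279, a covariance difference of 0.265. The simulated groups carried no real change, so these values cannot show how many of the 9273 shared calls the common controls add. Part of the excess may come from the shared controls, which at 3 are too few to give each comparison at least 2. Between rac-GR24 and brc1-2, which share no libraries, 2887 genes moved in opposite directions, 1466 and 1421 where independent lists would share 759 and 761, and 763 moved the same way (Fisher's exact test, two-sided, p = 2.9e-293). Pearson's r across the 19929 genes tested in both, which are not independent replicates, was -0.262. The Fisher's exact tests given here compare directions among genes called in both comparisons, not the excess over independent lists. They also treat genes as independent, which genes are not. Between rac-GR24 and decapitation 2454 moved in opposite directions, 1398 and 1056 where independent lists would share 828 and 743, and 1116 the same way (Fisher's exact p = 7.9e-123), with r of -0.175. Among genes changed at least 2-fold in both of these, 95 moved in opposite directions and 60 the same way (Fisher's exact p = 0.34).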

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

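The tests with the length trend removed or the counts halved, the splits, the tapetum sums, the floral organ count and the test with BRC1 left out of its list were chosen after the results were seen. A pair of lists was called in opposite directions for brc1-2 and decapitation against intact WT, and the direct comparison of decapitated WT with brc1-2 was past the threshold for both. Leaf photosynthesis genes had a median log2 difference of -0.61 between decapitated WT and brc1-2, and flavonoid and anthocyanin genes one of 0.45. The opposite calls of the photosynthesis list were lost with an estimated correlation (adjusted p = 0.28 for brc1-2 and 0.18 for decapitation), while those of the flavonoid list were kept (0.048 and 0.046), the former narrowly, since it was 0.057 with BRC1 also left out of the BRC1 list.

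Most tested genes were called in axillary tissue, 60.9% for brc1-2 and 62.9% for decapitation, and fold changes rose with gene length (Spearman's rho across genes 0.215 and 0.176). Removing each library's trend on length left 12788 calls for brc1-2 against 13123, so that trend does not account for most of the calls. Both mates of a pair appear to be counted, and halving every count left 13071 calls, but 1 factor for all genes and libraries hardly moves the test. What doubled counts add to the calls stays open, as does how far libraries of one group share plants, which the labels do not give.

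Each comparison of 3 against 3 allows 10 splits, too few for a share under 0.05; in all 4 comparisons 1 split, the real one, gave as many calls. The real splits called 5060 genes for rac-GR24, 13123 for brc1-2, 13556 for decapitation and 10448 for decapitated WT against brc1-2, and the highest of the other splits called 0 in each. Every other split mixes libraries of the 2 real groups, so real differences widen its spread and few calls can pass. The 0 calls therefore decide nothing.

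Transcripts of 9 members of the tapetum and pollen list were higher in brc1-2, but the pollen genes VGD1 and VGDH1 held 0 counts in every axillary library. Among the 9, MS1, CYP703A2, A9 and CYP704B1 passed the filter through brc1-2, where they were high. A single library with floral tissue was tested first with a bound of 10-fold between the summed CPM of the lowest brc1-2 and the highest intact WT library, and that bound was not met, at 4.40-fold, because LAP6 alone made up 93.1% to 94.6% of the sum in intact WT; without LAP6, left out after this was seen, the ratio was 47.6. A second test, chosen after the bound was not met, found sums of 32.5, 33.3 and 33.4 in the 3 brc1-2 libraries, a highest-to-lowest ratio of 1.03, against 6.79 to 7.40 in intact WT, which argues against 1 library alone. Developed floral organs in the brc1-2 harvests stay open: 6 of 6 floral organ identity genes were higher there, but these genes were chosen after their values were seen, so the count is no independent support. After decapitation the sums without LAP6 were 1.72 to 2.49, between 0.366 to 0.479 in intact WT and 22.8 to 23.5 in brc1-2, and whether such transcripts reflect the genotype, earlier outgrowth or the parts harvested was not tested.

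The opposite directions of rac-GR24 and brc1-2 were weighed against trends with gene length and expression level. With the length trend removed, opposite calls were 4.40 times as many as calls in the same direction, and in 10 of 10 bins of genes by mean expression r lay below -0.1, from -0.155 to -0.449. These values argue against either trend as the whole cause. Seedlings and axillary tissue differ in tissue, age and batch label, so a shared response to BRC1 remains a hypothesis.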

How the results depend on the processing

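Removing the length trend, halving the counts and leaving genes out of lists were chosen after seeing the data. Counts of calls stayed within 1.5 times of the main value except under stricter thresholds. At adjusted p under 0.01 rac-GR24 gave 3144 genes, and opposite calls numbered 1757 with brc1-2 and 1490 with decapitation. With a 2-fold minimum the calls were 768 for rac-GR24, 1542 for brc1-2, 1691 for decapitation and 1214 for decapitated WT against brc1-2, and the shared calls 581, 133 and 95, fewer because the criteria are stricter. With an estimated correlation 3 lists were called for rac-GR24 and 9 for decapitation, and with fry, which does not compare a list with other genes, 20 for brc1-2. With an estimated correlation and BRC1 left out of its list, 4 lists were called for brc1-2, and with the genes in both the Polycomb target and flowering lists left out, 8 for decapitated WT against brc1-2. Leaving out 1 library gave 3909 to 4980, 12202 to 12353, 12743 to 13148 and 9389 to 10493 calls. BRC1 ranged from 7.22 to 10.29 for rac-GR24, the highest without DMSO replicate 3, the DMSO library that held counts. Across these alternatives, apart from stricter thresholds, at least 74.7% of the genes called for rac-GR24 were called again, and at least 85.4% for the others.

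Low counts limit genes such as HB53 in seedlings, with 26 counts over the DMSO group. The replicate numbers do not pair the samples: same-numbered libraries had correlations of deviations from -0.058 to 0.086 in seedlings and 0.007 to 0.019 between intact and decapitated WT. Libraries with different numbers had -0.07 to 0.111 in seedlings, the highest for DMSO 3 with rac-GR24 2, and -0.029 to 0.021 in axillary tissue. Whether seedling libraries are paired in another order was not tested. With the replicate block rac-GR24 gave 4712 calls, decapitation 13406 and their opposite calls 2310; BRC1 changed by 7.60 and -2.09, and 11 and 14 lists were called. No paired analysis was possible for brc1-2 because 2 of its columns carry one number.

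For 431 values of named genes, 3901 of 3935 recomputed under other settings and 2506 of 2586 recomputed without 1 library kept direction and call. The directions that turned belonged to values not past the threshold, except REV for brc1-2 (0.15, past the threshold both ways), and the cause was not tested. Leaving out 1 library, ranges were -1.61 to 0.21 for BRC2, -0.43 to 0.09 for HB40 and -0.17 to 0.11 for LAP6 (rac-GR24); -0.59 to 0.06 for DLK2, -0.30 to 0.14 for BBX20, and -0.06 to 0.50 for HSP17.8 (brc1-2); -0.12 to 0.06 for BRC2 and -0.22 to 0.06 for OLEO4 (decapitation); and -0.05 to 0.03 for AT2G02540 (written as HB21 in the list, not the HD-ZIP gene), -0.59 to 0.31 for HB40 and 0 to 0.39 for OLEO4 (decapitated WT against brc1-2). With the length trend removed BBX20 was 0.09 and REV -0.08 (brc1-2), and SMXL2 -0.07 and OLEO4 0.04 (decapitation). SESA1 held 0 counts in intact WT and 2 in brc1-2, both under the floor, so no fold is given, and its fitted values of 0 to 3.13 leaving out 1 library depend on the prior count. AT2G02540 was 0.02 with no filter (decapitated WT against brc1-2). A few uncalled lists also turned: ribosomal proteins for rac-GR24 (adjusted p 0.23 to 0.95 leaving out 1 library), gibberellin for decapitated WT against brc1-2 (0.52 to 0.81) the clock for brc1-2 (0.7 with the length trend removed) and the BRC1 list without BRC1 for decapitated WT against brc1-2 (0.74, and 0.79 with an estimated correlation). With BRC1 in, that list had 0.38 to 0.72 leaving out 1 library.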

Other observations

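Gibberellin genes went both ways. GA2OX2, of a gibberellin-inactivating oxidase, rose by 1.39 after decapitation, fell by 0.91 in brc1-2 and rose by 1.75 on rac-GR24 in seedlings. Among floral organ genes, SEP3, AP3 and PI also rose after decapitation, by 0.66, 0.48 and 0.27, against 1.09, 0.91 and 1.34 in brc1-2.

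MYC2 and COL1, chosen after their values were seen, had total counts of 0 and 0 over the 9 axillary libraries. The hypothesis that reads in exons of more than 1 gene were left uncounted was written before its test. Of 1449 genes with over 90% of their exon bases shared with another gene 79.3% were at 0, against 18.7% of 23028 genes sharing none, a ratio of 4.25 by a test that could have come out the other way, and MYC2 shares 98.5% and COL1 100% of its exon bases. The shared and unshared genes were not matched for type, length or expression, so the ratio does not isolate the effect of counting. The zeros of such genes may reflect counting, and 9 of 465 list genes are of this kind.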
